A study of Mus musculus with 21 samples.

How the data were processed

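Bulk RNA sequencing was done on 21 libraries of mouse bone-marrow-derived macrophages in 12 groups, made of 6 treatments in a 4 h and a 48 h set. Per the labels' protocols, cells were lysed directly in buffer and libraries of full-length cDNA were made by a modified SmartSeq2 method, in which template switching is followed by amplification. No molecular identifiers are named there, so amplified reads are not independent molecules, and every interval and floor given covers counting error only. The values used are whole-number counts of reads per gene symbol, as deposited by the authors, for 34573 genes. Per the submitters' processing notes the tools were TopHat2, Bowtie, HTSeq and edgeR; their versions, settings, genome build and annotation are not given in the sources used here. Whether reads were counted by strand is not stated, so reads of overlapping genes cannot be told apart, and genes with near-identical copies are given as uncertain. Gene names were used as the count table gives them. The reference annotation used here served only for gene lengths and for overlapping genes, and no coordinates are given.

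Stimulated libraries were assigned from column names that give treatment, hours and number. Unstimulated columns are numbered 1 to 4 over both sets without hours. The controls lack the number 2, and the unstimulated labels lack only the first control of the 48 h set, so the numbers were read as replicate A, 1, B and 2. This is an inference from names. The fit with each unstimulated treatment merged over both sets (3 control, 4 DMM and 4 succinate libraries) does not use it, and was added after seeing the data. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

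Genes were kept when their counts passed the CPM of 10 reads in the median library in at least 2 libraries, with a total of at least 15. This left 6894 genes with all 21 libraries and 6812 without the library labelled LPS 48 h replicate 1. Libraries were scaled by trimmed mean of M values (TMM), and CPM values are counts per total of the kept genes times the TMM factor, scaled to a common size. Shares of ribosomal protein genes and of Fth1 are percent of all counts of a library. Total counts were 662186 to 1546867 per library. Genes with few counts at that depth have wide intervals.

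Each comparison was tested with edgeR's quasi-likelihood test with robust estimation, in 1 model of all 12 groups, with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05. A gene called rose or fell at an adjusted p under that threshold. The model had 9 residual degrees of freedom and a common biological coefficient of variation of 0.287 with 21 libraries, and 8 and 0.199 without the library labelled LPS 48 h replicate 1. Groups of 1 library were assumed to vary like the other groups. Values after ± are standard errors of log2 fold changes. Where all libraries of an arm held 0 counts, the fold is a bound against a floor of 3 counts over the group, and where they held 1 to 3 counts, a ratio of counts scaled by library size with its 95% counting interval. The group of LPS 48 h libraries was doubted after its values were seen, and the choice to take gene and list values from the 20-library fit came after that; the 21-library counts are those fixed before the data were examined.

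Before the data were examined, 30 gene lists were fixed, of responses and of markers of the macrophage and of other cell types the culture could hold. Of these, 24 had 5 or more tested genes and were tested with camera (limma) with a preset correlation of 0.01, with BH adjustment over the lists of a comparison. The further runs were camera with an estimated correlation and fry. The phrase adjusted over the list alone means BH adjustment within a list. The named genes were fixed by a rule, and some genes it took are not reported here. It took the 8 highest and 8 lowest log2 fold changes among called genes whose arms did not overlap and whose higher arm averaged at least 10 CPM (the 5 highest and 5 lowest for interactions and differences of effects, among called genes with a group mean of at least 10 CPM). Symbols of unnamed or predicted genes were left out of this part. It further took up to 4 genes per list with the smallest p, of which the text leaves out some, and a panel of 15 cytokine and metabolic genes. Where fewer than 10 genes were called, all of them are named. Ribosomal protein genes, Fth1 and genes of other cell types outside the lists were named after their values were seen.

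The alternatives fixed beforehand were DESeq2, median-of-ratios size factors, no filter on low counts, the libraries of 1 set alone, a replicate block and leaving out each library in turn. Added after seeing the data were the 20-library fit for comparisons that do not hold LPS 48 h, the merged unstimulated groups with 21 and with 20 libraries, DESeq2 with 20 libraries, and the 48 h set alone without the doubted library.

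The test was tried on simulated counts with 200 changed genes. For DMM then LPS against LPS at 4 h, on 6894 genes, it recovered 3% of genes changed 2-fold and 46% of those changed 4-fold with 21 libraries, with 3 false calls. On 6812 genes with 20 libraries it recovered 18% and 79%, with 7 false calls. For succinate then LPS against LPS at 4 h these shares were 0% and 20%, and 2% and 38%. For LPS against control at 48 h they were 3% and 18%, and 0% and 37%; for DMM then LPS against LPS at 48 h, 3% and 43%, and 3% and 48%. Genes changed 2-fold were thus mostly not detectable. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.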

Results

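The transcriptomes of mouse bone-marrow-derived macrophages (BMDMs) were profiled by bulk RNA sequencing. BMDMs are macrophages grown in culture from marrow precursors, here for 6 days with L929-conditioned medium supplying the growth factor M-CSF. Cells stayed untreated or received succinate or dimethyl malonate (DMM) for 3 h. Succinate is an intermediate of the tricarboxylic acid (TCA) cycle and the substrate of succinate dehydrogenase; DMM is an ester that releases malonate, a competitive inhibitor of that enzyme. Part of the cultures then received lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages, for 4 or 48 h. The doses are not given in the sources used here. The 21 libraries formed 12 groups, 11 libraries in a 4 h set (replicates A and B) and 10 in a 48 h set (replicates 1 and 2). Of the groups, 9 held 2 libraries, and control 48 h, succinate then LPS 4 h and succinate then LPS 48 h held 1 each. Which unstimulated libraries belong to which set was inferred from their numbering. Total counts ran from 662186 in DMM 4 h replicate A to 1546867 in DMM then LPS 4 h replicate A. The comparisons ask what LPS changed, what DMM and succinate changed without LPS, what they changed under LPS, and whether the changes of the 4 h and 48 h sets differed.

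The acute-phase transcript Saa3, an LPS-induced serum amyloid gene, separated the libraries by label with 1 exception. It lay at 109.3 CPM (counts scaled to a common library size) or lower in the 11 libraries labelled unstimulated and at 54610.2 CPM or higher in all other stimulated libraries. The library labelled LPS 48 h replicate 1 held 33.8 CPM of Saa3, against 98269.4 CPM in replicate 2. Its Il1b, the gene of the pyrogenic cytokine interleukin-1 beta, was at 0.89 CPM against 5199.6 CPM in replicate 2. Over genes, its counts lay closer to those of DMM 48 h replicate 1 than the counts of any other of the 210 library pairs lay to each other (chi-square per degree of freedom 1.19, p = 7.06e-28, a comparison of those libraries). The counts of every comparison below are given with all 21 libraries and without this library (20 libraries); gene and list values come from the 20-library fit. That choice was made after seeing the data. In that fit the LPS 48 h group held 1 library, which was assumed to vary like the other groups.

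**Figure D1:**
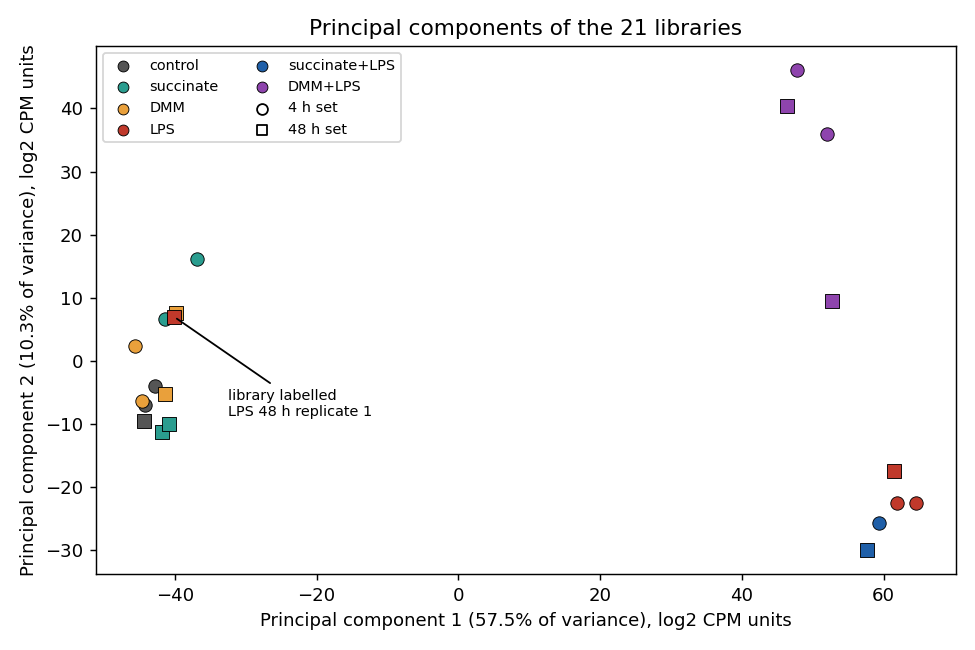
Principal components of log2 CPM over the tested genes, 1 point per library, with the share of variance on each axis (57.5% and 10.3%). Colour gives the treatment and shape the set; the library labelled LPS 48 h replicate 1 lies among the unstimulated libraries.

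LPS for 4 h raised all 10 measured pro-inflammatory mediators and all 12 chemokines, the attractants of other leukocytes. Il1b rose by 11.18 ± 0.67 and Tnf, the gene of tumour necrosis factor, by 6.04 ± 0.39 on the log2 scale (log2 fold change ± SE, 2 libraries per group). Irg1 (also called Acod1), the itaconate-producing enzyme, rose by 9.97 ± 0.62. Ccl7, a monocyte attractant, was at least 679-fold higher and Cxcl2, a neutrophil attractant, at least 156-fold higher, and Ccl2 and Ccl5 rose by 8.99 to 9.17. The arginine hydrolase Arg1 was at least 218-fold and the uridine phosphorylase Upp1 at least 175-fold higher. Saa3 rose by 11.05 ± 0.74, the siderophore-binding Lcn2 3980-fold (95% counting interval 1360 to 19300), the protease inhibitor Slpi 3540-fold (95% counting interval 635 to 140000) and the prostaglandin E synthase Ptges 1350-fold (95% counting interval 460 to 6530). The further cytokine-panel genes Nos2, Ptgs2, Il1rn, Hif1a, Slc2a1, Il1a and Cxcl10 were also called higher. Il6, Il10, Il12b and Ifnb1 held at most 8 counts in any library and were not tested.

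In the same comparison 26 of 34 type I interferon response genes rose (27 adjusted over the list alone), among them the transcription factor Irf7 (5.31 ± 0.45) and the nucleic acid sensor Zbp1 (5.13 ± 0.40). The feedback regulators Socs3 and Irak3 rose, with 14 of 15 members of their list. Of 20 glycolysis genes 17 rose and 1 fell; the glucose transporter Slc2a1 rose by 4.40 ± 0.33 and the lactate exporter Slc16a3 by 6.28 ± 0.47. Further targets of the hypoxia factor HIF-1 rose in 10 of 16 cases (Hif1a itself, 3.20 ± 0.36). NRF2 antioxidant genes rose in 17 of 25, with 2 lower (Hmox1, the haem oxygenase, 6.37 ± 0.50; Gsr, the glutathione reductase, 5.15 ± 0.39). Cell cycle genes fell in 31 of 34 cases (Top2a, -4.43 ± 0.38; Mcm6, -3.06 ± 0.34), cyclin B2 (Ccnb2) by at least 26.9-fold. Cholesterol synthesis genes fell in 18 of 22 cases (Fdps, -3.83 ± 0.42; Insig1, -2.59 ± 0.32). Of the lipid-handling genes, 6 of 15 fell with the fatty acid synthase Fasn (-3.76 ± 0.35) while 2 rose with the cholesterol exporter Abca1 (2.14 ± 0.28). The prostaglandin dehydrogenase Hpgd was at least 86.7-fold lower, Cd28 232-fold (95% counting interval 41.3 to 9210) lower, and Cd83, Stmn1, Entpd1, Mical1 and Gpx3 were lower by at least 12.1 to 18.6-fold. Macrophage identity genes moved both ways, with 7 of 19 higher (the scavenger receptor Msr1, 6.35 ± 0.48) and 6 lower (the lipid receptor Trem2, -6.23 ± 0.41).

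The list tests with camera gave adjusted p = 6.31e-29 for pro-inflammatory mediators, 6.55e-20 for chemokines, 4.75e-16 for interferon, 5.36e-18 for feedback, 4.43e-18 for cell cycle and 2.05e-11 for cholesterol genes. These calls held with an estimated correlation (adjusted p of at most 0.00957). Glycolysis had adjusted p = 4.16e-14, and 0.0499 with an estimated correlation. The calls of HIF-1 targets (1.78e-06), NRF2 genes (8.10e-08) and lipid handling (0.00486) were lost with an estimated correlation, at adjusted p = 0.0716, 0.0777 and 0.0764. Further called lists were heat shock and immediate early genes (4 of 13 higher, Ier3 8.11 ± 0.54; camera adjusted p = 0.0239, and adjusted p = 0.0716 with an estimated correlation) and apoptosis and survival genes (8 of 20 higher, 1 lower, Birc3 3.47 ± 0.35; camera adjusted p = 0.0176, and adjusted p = 0.0566 with an estimated correlation). The unfolded protein response (8 of 20 higher; camera adjusted p = 0.0484, and adjusted p = 0.188 with an estimated correlation) and lysosome lists (11 of 29 lower, 3 higher; camera adjusted p = 0.0206, and adjusted p = 0.599 with an estimated correlation) were called as well. The succinate handling list was called higher (3 of 11; camera adjusted p = 0.026, and adjusted p = 0.0716 with an estimated correlation). The TCA cycle, oxidative phosphorylation, mitochondrially encoded, pentose phosphate, ATF4 target, alternative activation, MHC class II and macrophage identity lists were not called (adjusted p between 0.0997 and 0.881). The 5 measured markers of neutrophils and their precursors all rose (camera adjusted p = 1.34e-10, and adjusted p = 0.00183 with an estimated correlation), Mmp9 276-fold (95% counting interval 49.2 to 10900) and S100a8 at least 33.9-fold. Of other transcripts of neutrophils, S100a9 stayed at or below 1.33 CPM and Ly6g and Ltf at 0 in every library. edgeR's quasi-likelihood test called 1286 genes with all 21 libraries (760 higher, 526 lower), 1869 with 20 (1030 higher, 839 lower), and 1956 in the planned fit of the 4 h set alone. With 21 libraries, leaving out either control or either LPS library left 418 (without control replicate A) to 594 genes (without LPS replicate B).

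LPS for 48 h, in the comparison of the library labelled LPS 48 h replicate 2 with the lone control library, raised cytokine and acute-phase genes. Il1b was 1740-fold (95% counting interval 594 to 8430) higher, Irg1 5350-fold (95% counting interval 1480 to 44200) and Tnf higher by 5.67 ± 0.55 on the log2 scale. The haptoglobin gene Hp was at least 479-fold higher, the NAD hydrolase Cd38 at least 314-fold, Slpi at least 214-fold, the scavenger receptor Marco at least 200-fold and Mmp14 at least 92.9-fold. The arginine transporter Slc7a2 was at least 85.8-fold and Lcn2 was 5740-fold (95% counting interval 1030 to 227000) higher. All 10 pro-inflammatory mediators, 9 of 12 chemokines (Ccl5, 10.14 ± 0.91; Ccl3, 4.84 ± 0.62) and 30 of 34 interferon genes (Irf7, 5.83 ± 0.65; Usp18, 4.04 ± 0.46) rose. So did 14 of 15 feedback regulators and 17 of 20 glycolysis genes (Slc16a3, 6.83 ± 0.70). Cell cycle genes fell in 29 of 34 cases (Ccnb2 and Ccna2 by at least 21.5 to 25.4-fold), cholesterol genes in 12 of 22 (Fdps, -3.60 ± 0.52). Ighm was at least 39.9-fold lower, Crip1 287-fold (95% counting interval 51.1 to 11400) lower. Cks1b, Scd1, Rgs2 and Cdc25b were lower by at least 10.2 to 13.2-fold. The mannose receptor gene Mrc1 (-7.42 ± 0.74) and Trem2 (-7.37 ± 0.65) fell. The panel genes Nos2, Ptgs2, Il1rn, Hif1a, Slc2a1, Arg1, Il1a and Cxcl10 were called higher as well.

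camera gave adjusted p = 7.37e-25 for pro-inflammatory, 2.46e-17 for chemokine, 2.62e-26 for interferon, 1.14e-15 for glycolysis, 9.68e-22 for cell cycle and 4.60e-08 for cholesterol genes, each kept with an estimated correlation (adjusted p of at most 0.0337). HIF-1 targets (7 of 16 higher) had camera adjusted p = 5.32e-06, and adjusted p = 0.0692 with an estimated correlation. The 5 neutrophil-marker genes were all higher (camera adjusted p = 1.37e-07, and adjusted p = 0.00313 with an estimated correlation). Heat shock and immediate early (5 of 13), ATF4 target (3 of 21) and succinate handling genes (3 of 11) were called higher as lists (camera adjusted p from 0.000598 to 0.0123, and adjusted p from 0.0141 to 0.0491 with an estimated correlation). So were feedback regulators (camera adjusted p = 4.51e-17, and adjusted p = 0.00857 with an estimated correlation). NRF2 genes (9 of 25 higher) and apoptosis genes (7 of 20 higher) were called higher and mitochondrially encoded transcripts (3 of 11) lower. These calls were lost with an estimated correlation (camera adjusted p from 0.000711 to 0.0352, and adjusted p from 0.0692 to 0.371 with an estimated correlation). With all 21 libraries edgeR called 0 genes (769 at an unadjusted p under 0.05; DESeq2 called 114). Without the library labelled LPS 48 h replicate 1 it called 1217 (692 higher, 525 lower). This sets 1 library against 1, so the test rests on the spread of the other groups.

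DMM alone in the 4 h set raised the chemokine receptor Ccr2 and cyclin D1. Ccr2 (3.46 ± 0.61), cyclin D1 (Ccnd1, 2.37 ± 0.35), Khsrp, Ing5, Ebi3 and the clone-named AC122837.1 (2.46 to 2.78) rose. The coagulation factor gene F13a1 was at least 7.94-fold, Pf4 at least 4.21-fold and Lpcat1 11.1-fold (95% counting interval 2.69 to 97.7) higher. The proton pump subunit Atp6v0d2 (-2.88 ± 0.53), the chemokine receptor Cxcr4 (-2.21 ± 0.45), the neuropeptide Npy (-1.83 ± 0.34), the betaine transporter Slc6a12 (-1.77 ± 0.33), Zfand2a, Slfn5 and Rnh1 (-1.47 to -1.58) fell. The inositol transporter Slc5a3 fell (-1.85 ± 0.30), with uncertain counts because it overlaps Mrps6 in the annotation. Cell cycle genes were higher as a list, with 1 of 34 called over all genes and 9 adjusted over the list alone (camera adjusted p = 3.45e-11, and adjusted p = 0.000896 with an estimated correlation). Lysosome genes had a median of -0.43 (1 of 29 lower; camera adjusted p = 7.57e-06, and adjusted p = 0.523 with an estimated correlation). Interferon genes had one of -0.45, with 0 called over all genes and 2 of 34 lower when adjusted over the list alone (camera adjusted p = 0.000615, and adjusted p = 0.416 with an estimated correlation). Cholesterol genes had one of 0.38 (camera adjusted p = 0.0167, and adjusted p = 0.416 with an estimated correlation). No panel gene was called (Il1b, 0.83 ± 0.88; Tnf, -0.17 ± 0.63). edgeR called 0 genes with all 21 libraries (421 at an unadjusted p under 0.05; DESeq2 24), 71 with 20 (52 higher, 19 lower) and 104 in the 4 h set alone. With 21 libraries it called 0 without DMM replicate A (283 at an unadjusted p under 0.05) and 10 without DMM replicate B. At equal depth these DMM libraries had the highest chi-square per degree of freedom of any pair within a group, the library labelled LPS 48 h replicate 1 aside (10.838), and replicate B lay closer to control replicate B (4.019).

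In the 48 h set DMM alone raised F13a1 by 3.11 ± 0.61 and lowered Slc5a3 (-2.55 ± 0.38), the 2 genes called with 20 libraries. No cholesterol synthesis gene was called over all genes, and 10 of 22 were lower when adjusted over the list alone (median -0.93; camera adjusted p = 3.27e-14, and adjusted p = 0.00517 with an estimated correlation). Cell cycle genes had a median of 0.43 (camera adjusted p = 3.77e-06, and adjusted p = 0.00517 with an estimated correlation). Among 9 genes of antigen presentation on MHC class II and co-stimulation, 5 were higher and 1 (the lysosomal protease Ctss, -1.13 ± 0.48) lower when adjusted over the list alone (camera adjusted p = 5.04e-05, and adjusted p = 0.0144 with an estimated correlation). Oxidative phosphorylation, lysosome and lipid-handling genes had lower medians (-0.39, -0.42 and -0.31) and the neutrophil markers a higher one. Each call was lost with an estimated correlation (camera adjusted p from 6.53e-06 to 0.041, and adjusted p from 0.16 to 0.616 with an estimated correlation). With all 21 libraries edgeR called 0 genes (223 at an unadjusted p under 0.05; DESeq2 4). The control group of this set held 1 library.

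Succinate alone changed no gene past the test in either set with 21 or with 20 libraries. Il1b was at 1.62 ± 0.77 and Tnf at -0.06 ± 0.58 in the 4 h set (log2 fold change ± SE), and no panel gene was called in either set. Oxidative phosphorylation genes had a median of -0.36 in the 4 h set (camera adjusted p = 9.76e-06, and adjusted p = 0.638 with an estimated correlation). Lysosome genes had one of -0.32 (camera adjusted p = 0.00187, and adjusted p = 0.641 with an estimated correlation). In the 48 h set, interferon genes had a median of -0.36 (camera adjusted p = 0.00189, and adjusted p = 0.583 with an estimated correlation). Cholesterol genes had one of 0.30 (camera adjusted p = 0.0078, and adjusted p = 0.489 with an estimated correlation). Lipid-handling genes had a median of 0.48 (camera adjusted p = 0.0078, and adjusted p = 0.489 with an estimated correlation). No member of these lists was called over all genes or when adjusted over the list alone. edgeR called 0 genes in the 4 h set with 21 libraries (310 at an unadjusted p under 0.05; DESeq2 1) and 0 with 20 (518; DESeq2 0). The planned fit of the 4 h set alone called 3, the phospholipase Pla2g7 and Ppp1r8 higher and Mir5105 lower. The 48 h set gave 0 and 0 (136 and 247 at an unadjusted p under 0.05; DESeq2 2 and 0).

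DMM before LPS, against LPS alone in the 4 h set, shifted inflammatory mediators in both directions. The inducible nitric oxide synthase Nos2 (1.60 ± 0.29), the prostaglandin synthase Ptgs2 (1.45 ± 0.25), the interleukin-1 receptor antagonist Il1rn (0.97 ± 0.31) and Arg1 (2.61 ± 0.41) rose. Tnf (-1.58 ± 0.27), Ptges (-2.06 ± 0.35), Irg1 (-1.61 ± 0.41) and Hif1a (-0.98 ± 0.33) fell. Il1b, at 8056 CPM with LPS alone, was not called (-0.73 ± 0.39), nor were Il1a, Slc2a1 and Cxcl10. The elastase Mmp12 rose by 3.23 ± 0.36 and the muscle-type adenylosuccinate synthase Adssl1 was 44-fold (95% counting interval 7.63 to 1760) higher. Mical1 was at least 6.17-fold higher. Cit, Rhov, Ddah2, Gypc and Eif2d, with 1 to 3 counts under LPS alone, were 10.1 to 21-fold higher (lowest bound of their 95% counting intervals 3.16, for Ddah2). The succinate and dicarboxylate transporter Slc13a3 (-5.07 ± 0.46), Marco (-4.06 ± 0.34) and the fatty acid receptor Gpr84 (-3.98 ± 0.35) fell. Wdr38 was 16.7-fold (95% counting interval 4.12 to 147) lower, and the clone-named AC165259.1 fell (-3.68 ± 0.43). The translation genes Eef1a1 (-4.10 ± 0.46) and Rpl3 (-4.08 ± 0.38) and the pseudogene Actg-ps1 (-5.06 ± 1.09) fell too, with counts that are uncertain because near-identical copies share their reads.

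**Figure D2:**
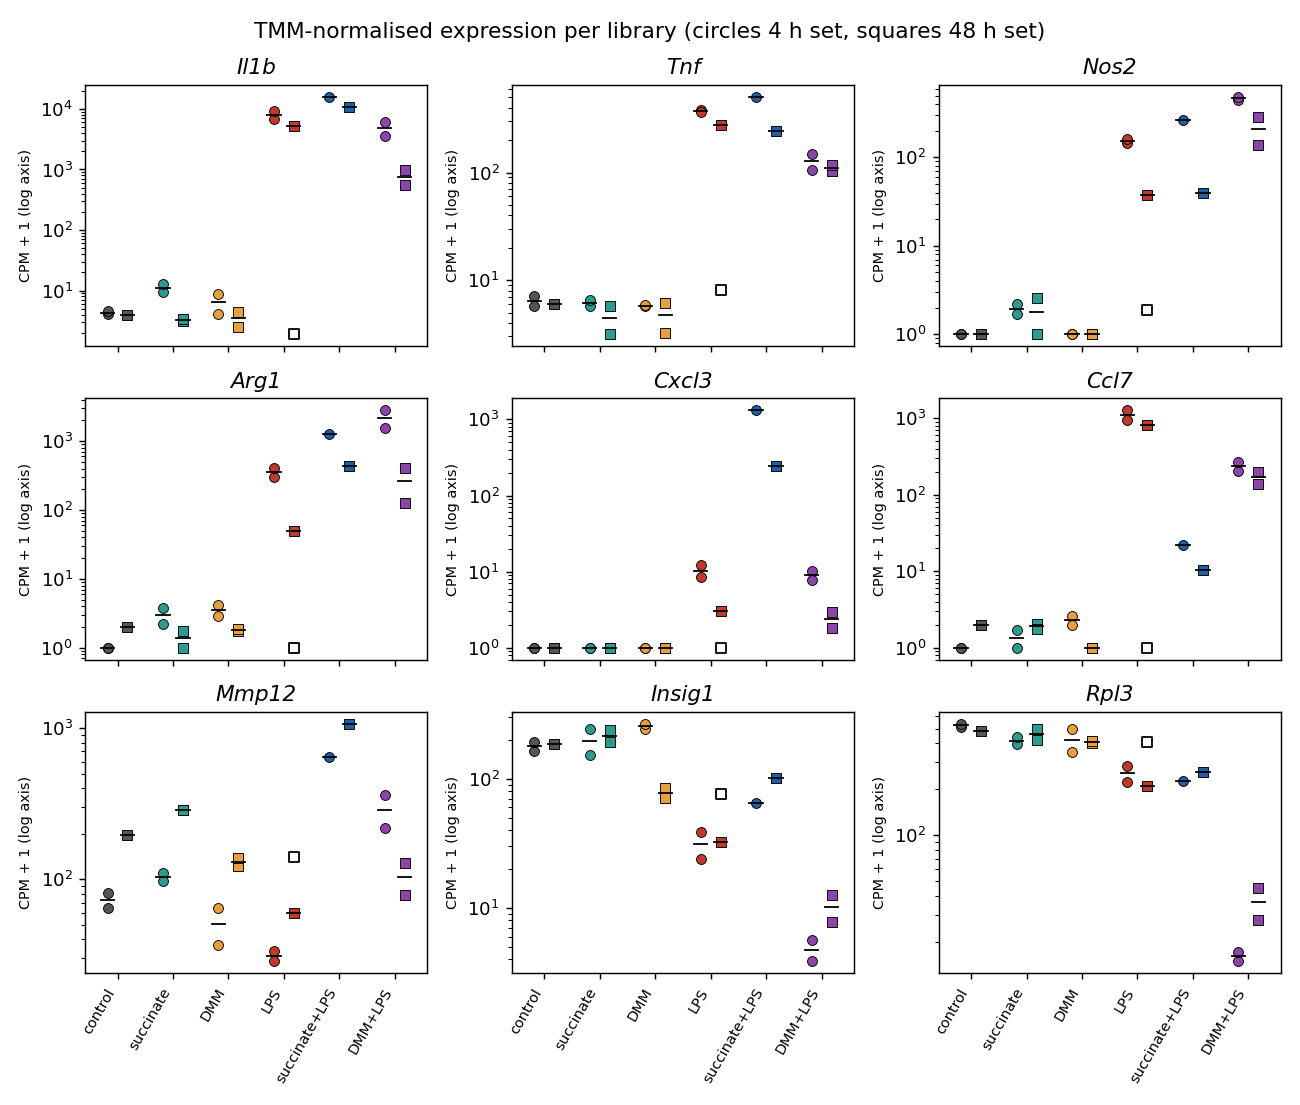
CPM + 1 per library on a log axis for Il1b, Tnf, Nos2, Arg1, Cxcl3, Ccl7, Mmp12, Insig1 and Rpl3 in the 12 groups; points are libraries, bars group means, and the open square is the library labelled LPS 48 h replicate 1. Nos2, Arg1 and Mmp12 lay higher, and Tnf, Insig1 and Rpl3 lower, in both DMM then LPS groups than in LPS alone without the open square.

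By list (not matched on gene length), chemokines fell in 7 of 12 (Ccl7, -2.26 ± 0.30; Cxcl2, -1.68 ± 0.29; camera adjusted p = 0.000746, and adjusted p = 0.342 with an estimated correlation). Interferon genes fell in 16 of 34 (Isg15, -2.57 ± 0.40; Zbp1, -1.81 ± 0.28; 2 higher and 18 lower adjusted over the list alone; camera adjusted p = 0.000126, and adjusted p = 0.342 with an estimated correlation). Chaperones and targets of the unfolded protein response fell in 10 of 20 cases (15 adjusted over the list alone), among them calreticulin (Calr, -2.17 ± 0.34) and BiP (Hspa5, -1.83 ± 0.34; camera adjusted p = 0.0001, and adjusted p = 0.19 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 25 of 57 cases, 32 adjusted over the list alone, with none higher (Cox5b, -2.18 ± 0.30; camera adjusted p = 1.53e-07, and adjusted p = 0.45 with an estimated correlation). Mitochondrially encoded transcripts fell in 4 of 11 cases (camera adjusted p = 0.00662, and adjusted p = 0.569 with an estimated correlation). Succinate handling genes fell in 5 of 11, the dehydrogenase subunits Sdha (-0.88 ± 0.27) and Sdhb among them (camera adjusted p = 0.0447, and adjusted p = 0.342 with an estimated correlation). Macrophage identity genes fell in 10 of 19 cases, 1 rose (complement C1qa, -2.84 ± 0.42; the integrin Itgam, -2.04 ± 0.38; camera adjusted p = 0.0001, and adjusted p = 0.408 with an estimated correlation). Of the neutrophil markers, Mmp9 fell (-2.74 ± 0.36) and S100a8 rose (2.25 ± 0.29). Pro-inflammatory mediators as a list were not called by camera (2 of 10 higher, 4 lower; adjusted p = 0.477). The sterol sensor Insig1 (-2.91 ± 0.46) fell. Cytosolic ribosomal protein genes, a group looked at after the values were seen, had a median log2 fold change of -2.26. Their share of all counts was 0.55% and 0.60% with DMM then LPS against 1.59% and 1.68% with LPS alone; the iron storage gene Fth1 took 11.02% and 10.59% against 5.25% and 5.61%.

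edgeR called 464 genes with all 21 libraries (103 higher, 361 lower; 29 and 399 with DESeq2), 1230 with 20 (332 higher, 898 lower) and 1435 in the 4 h set alone. With 21 libraries, 14 genes were called without DMM then LPS replicate A and 123 to 133 without LPS replicate B, LPS replicate A or DMM then LPS replicate B.

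In the 48 h set, DMM before LPS lowered Il1b (-2.75 ± 0.47), Tnf (-1.31 ± 0.31), Ccl7 (-2.25 ± 0.34) and the gelatinase Mmp9 (-3.39 ± 0.45) against the library labelled LPS 48 h replicate 2. The protease inhibitor Serpinb2 (-4.01 ± 0.43), Gpr84 (-3.89 ± 0.39), the cholesterol 25-hydroxylase Ch25h (-3.82 ± 0.40), Trem3 (-3.06 ± 0.84), Slc7a2 (-2.61 ± 0.31) and Rpl3 (-2.55 ± 0.39; reads shared with copies) fell. Nos2 (2.55 ± 0.43), Arg1 (2.47 ± 0.58), Trem2 (3.25 ± 0.65; -2.53 ± 1.11 and not called with 21 libraries) and the scavenger protein Cd5l (3.54 ± 0.48) rose. Tceal8, Cyp4f18, Dcn and Ttll1 were at least 3.38 to 3.93-fold higher and Dgka, Wdr24 and Glipr2, with 1 count in the LPS library, 14.2 to 27.6-fold (lowest bound of their 95% counting intervals 2.38, for Glipr2). Irg1 (-0.79 ± 0.48), Hif1a (-0.58 ± 0.40), Ptgs2 (-0.06 ± 0.35) and Il1rn (1.38 ± 0.41) were not called, nor were Il1a, Slc2a1 and Cxcl10. Unfolded protein response genes fell in 3 of 20 cases (9 adjusted over the list alone; Hspa5, -1.64 ± 0.39; camera adjusted p = 4.23e-07, and adjusted p = 0.0533 with an estimated correlation). Chemokines fell in 3 of 12 (4 adjusted over the list alone; camera adjusted p = 0.00109, and adjusted p = 0.295 with an estimated correlation). Oxidative phosphorylation genes fell in 1 of 57 (median -0.52; camera adjusted p = 2.18e-05, and adjusted p = 0.466 with an estimated correlation) and glycolysis genes in 1 of 20 (camera adjusted p = 0.00903, and adjusted p = 0.466 with an estimated correlation). Antigen presentation genes had a median of 1.23 (0.83 with genes at 0 counts at their bounds, -0.17 with 21 libraries; 1 of 9 higher adjusted over the list alone; camera adjusted p = 0.00903, and adjusted p = 0.144 with an estimated correlation). Pro-inflammatory, mitochondrially encoded, heat shock and macrophage identity lists had lower medians. Their calls were lost with an estimated correlation (camera adjusted p from 0.0288 to 0.0454, and adjusted p from 0.265 to 0.495 with an estimated correlation). The replicates of DMM then LPS differed (values looked up after the tests). Against LPS replicate 2, the median differences in log2 CPM (prior count 2) of replicates 1 and 2 were -0.90 and -0.27 for pro-inflammatory, -0.92 and -0.34 for mitochondrially encoded and -1.23 and -0.46 for macrophage identity genes, and -1.22 and -0.33 for chemokines, -1.05 and -0.20 for oxidative phosphorylation, -0.88 and -0.06 for glycolysis, -0.40 and -0.34 for heat shock, -0.79 and -0.68 for unfolded protein response and 0.99 and 0.73 for antigen presentation genes. The summed CPM of replicate 2 was not below LPS for pro-inflammatory, mitochondrially encoded, macrophage identity and chemokine genes (29970 against 21390 for the last), and that of replicate 1 was below it for antigen presentation genes (6084 against 8387). With all 21 libraries camera called the chemokine (median 0.04), glycolysis and pro-inflammatory lists higher (adjusted p = 0.0361, 0.0342 and 0.00461). All 3 were lost with an estimated correlation (adjusted p = 0.624, 0.629 and 0.557). edgeR called 52 genes with 21 libraries (11 higher, 41 lower) and 171 with 20 (43 higher, 128 lower), 26 of them shared. With 21 libraries, 0 genes were called without DMM then LPS replicate 1 (727 at an unadjusted p under 0.05) and 1275 without LPS replicate 2, where the library labelled LPS 48 h replicate 1 stood alone for LPS and Il1b, Tnf, Ccl7, Mmp9, Serpinb2, Gpr84 and Slc7a2 turned to higher.

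The effect of DMM was tested against its effect without LPS by an interaction. In the 4 h set C1qa (-3.46 ± 0.56), the scavenger receptor Cd36 (-2.55 ± 0.49), Calr (-2.03 ± 0.47) and the inflammasome gene Nlrp3 (-3.42 ± 0.67) had lower DMM effects under LPS than without it. The glutathione transferase Gstm1 had a higher one (2.19 ± 0.42). Atp6v0d2, Tcp11l2 and Adssl1 were called higher with 1 or 2 counts under LPS alone, so that no size is given. Rhov and Mical1 were called higher, and Slc13a3, Tmem176a, Cmklr1, Pf4 and F13a1 lower, each with a group at 0 counts and no size given. Of the panel only Irg1 was called (-2.42 ± 0.72). Unfolded protein response genes were lower in 7 of 20 cases (camera adjusted p = 0.000243, and adjusted p = 0.271 with an estimated correlation). Macrophage identity genes were lower in 6 and higher in 1 of 19 (camera adjusted p = 0.000243, and adjusted p = 0.554 with an estimated correlation). Oxidative phosphorylation (4 of 57), mitochondrially encoded (2 of 11), cholesterol (3 of 22) and pro-inflammatory genes (2 of 10) were called lower as lists. These calls were lost with an estimated correlation (camera adjusted p from 0.000243 to 0.0448, and adjusted p from 0.554 to 0.636 with an estimated correlation). For the 48 h set, Cd5l (3.67 ± 0.58), Trem2 (3.72 ± 0.74; -2.08 ± 1.70 and not called with 21 libraries), Syngr1, Anpep and Lrp12 (2.83 to 3.39) had higher, and Ch25h (-5.57 ± 0.60) and F13a1 (-3.57 ± 0.80) lower DMM effects under LPS. Gpr84, Itgal and Slc7a2 were called lower with 2, 2 and 0 counts in the control library. No panel gene was called. The unfolded protein response list had camera adjusted p = 4.90e-06, and adjusted p = 0.083 with an estimated correlation. The chemokine and glycolysis lists were lower and the lysosome list higher (camera adjusted p from 0.0119 to 0.0419, and adjusted p from 0.536 to 0.718 with an estimated correlation). edgeR called 78 genes in the 4 h set with 21 libraries (13 higher, 65 lower), 447 with 20 (86 higher, 361 lower) and 640 in the 4 h set alone. Leaving out any 1 library of its 4 groups left 5 (without DMM then LPS replicate A) to 42 genes (without DMM replicate A). It called 2 in the 48 h set (0 higher, 2 lower; 1 and 2 with median-of-ratios size factors) and 22 (6 higher, 16 lower). With 21 libraries it called 613 there without LPS replicate 2, and 0 without DMM replicate 2 or DMM then LPS replicate 2 (458 and 608 at an unadjusted p under 0.05; DESeq2 27 with all libraries).

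Succinate before LPS for 4 h, against LPS alone, raised the neutrophil attractants Cxcl3 (7.11 ± 0.36), Cxcl1 (4.46 ± 0.41) and Cxcl2 (2.19 ± 0.32) and lowered the monocyte attractant Ccl7 (-5.71 ± 0.52), as log2 fold changes (1 succinate library, 2 LPS libraries). The metalloproteinases Mmp9 (4.71 ± 0.38), Mmp12 (4.39 ± 0.40) and Mmp8 (4.09 ± 0.32) rose, with platelet factor Pf4 (4.14 ± 0.36), Trem2 (2.86 ± 0.47), Arg1 (1.80 ± 0.46) and Ptgs2 (1.42 ± 0.30). The desaturase Scd1 was 16.1-fold (95% counting interval 4.79 to 84.8) and Cyp4f18 29.1-fold (95% counting interval 4.3 to 1240) higher. Il1rn (-2.15 ± 0.44) and Slfn4 (-3.75 ± 0.53) fell. The nucleoside transporter Slc28a2 was at least 12.8-fold and Fam114a1 at least 3.04-fold lower. Slc13a3 was 19.3-fold (95% counting interval 6.46 to 94.6), Ifi205 16.1-fold (95% counting interval 5.38 to 79.2) and Ly86 14-fold (95% counting interval 3.74 to 118) lower. Il1b (0.96 ± 0.47), Tnf (0.42 ± 0.31), Nos2 (0.77 ± 0.35), Irg1 (0.21 ± 0.49), Hif1a (0.24 ± 0.39), Slc2a1, Il1a and Cxcl10 were not called.

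Interferon response genes fell in 11 of 34 cases, 23 adjusted over the list alone (Zbp1, -2.06 ± 0.39; Ifi204, -2.12 ± 0.41; camera adjusted p = 3.70e-25, and adjusted p = 0.00471 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 22, 13 adjusted over the list alone (Fdps, 3.23 ± 0.52; Sqle, 2.52 ± 0.48; camera adjusted p = 5.63e-19, and adjusted p = 0.00213 with an estimated correlation). NRF2 antioxidant genes rose in 4 of 25 cases, 7 adjusted over the list alone (the cystine importer Slc7a11, 1.33 ± 0.30; Gclm, 1.66 ± 0.32; camera adjusted p = 8.08e-05, and adjusted p = 0.396 with an estimated correlation). Lipid-handling genes rose in 3 of 15 (Fasn, 2.42 ± 0.42; camera adjusted p = 0.0328, and adjusted p = 0.337 with an estimated correlation). Glycolysis and mitochondrially encoded lists had higher medians (camera adjusted p from 0.00222 to 0.0328, and adjusted p from 0.581 to 0.63 with an estimated correlation). Chemokines moved both ways (3 of 12 higher, 4 lower; adjusted p = 0.579). The neutrophil-marker list rose through Mmp8, Mmp9 and S100a8 (3.37 ± 0.32; camera adjusted p = 1.92e-21, and adjusted p = 0.000205 with an estimated correlation), beside S100a9 at 1.33 CPM and Ly6g at 0 in that library. Beside Pf4, at 207 CPM, the other platelet-lineage transcripts Ppbp and Itga2b were at 0 in that library. edgeR called 17 genes with 21 libraries (14 higher, 3 lower), 131 with 20 (66 higher, 65 lower) and 173 in the 4 h set alone. With 21 libraries 7 genes were called without LPS replicate A and 6 without LPS replicate B; the lone succinate library was assumed to vary like the other groups.

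**Figure D3:**
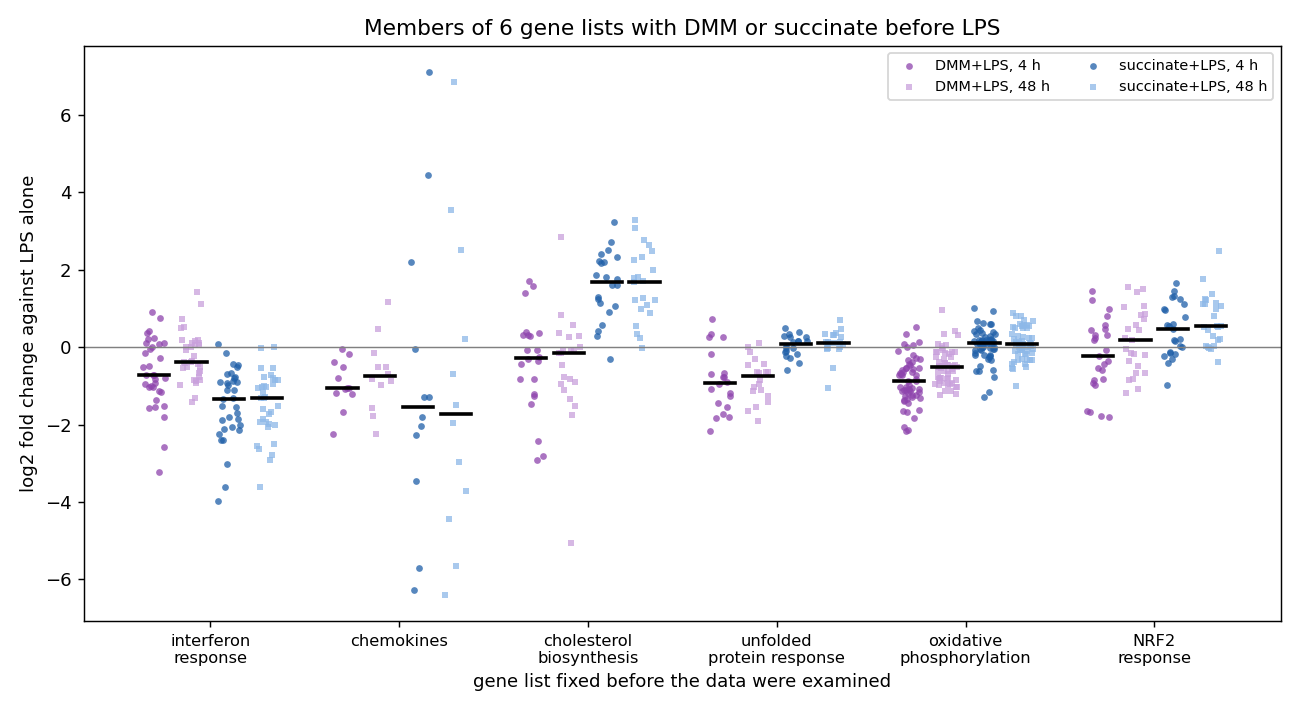
Log2 fold change against LPS alone of the measured members of 6 gene lists (type I interferon response, chemokines, cholesterol biosynthesis, unfolded protein response, oxidative phosphorylation and NRF2 antioxidant response) in the 4 comparisons of DMM or succinate before LPS, from the 20-library fit. Each point is a gene and each bar the median of its list; with succinate, the interferon medians were -1.33 and -1.30 and the cholesterol medians 1.69 and 1.69 in the 4 h and 48 h sets.

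With 1 library on each side in the 48 h set, succinate before LPS had Cxcl3 121-fold (95% counting interval 33.1 to 1010) higher. Higher too were Pf4 (5.26 ± 0.47), Trem2 (4.32 ± 0.67), Mmp12 (4.21 ± 0.50), Mmp9 (3.61 ± 0.48), Mmp8 (3.46 ± 0.42) and Arg1 (3.20 ± 0.64). Lower were Ccl7 (-6.40 ± 0.58), Ccl12 (-3.73 ± 0.55), Ccl2 (-2.97 ± 0.56) and Il1rn (-2.64 ± 0.51). The interferon-inducible Cxcl10 was 23.3-fold (95% counting interval 6.15 to 197) lower and Mx1 13-fold (95% counting interval 3.29 to 112) lower; the prothrombinase Fgl2 (-4.66 ± 0.60), Slc28a2 (-3.22 ± 0.60) and Ifit2 (-2.92 ± 0.55) fell. Scd1 was at least 5.4-fold higher, and Crip1, Clec4n and Prune2, with 1 or 2 counts in the LPS library, 15.1 to 20.8-fold (lowest bound of their 95% counting intervals 2.26, for Prune2). Neither Trem2 (-1.46 ± 1.37) nor Crip1 (-2.57 ± 1.64) was higher or called with 21 libraries. Il1b (1.07 ± 0.56), Tnf (-0.16 ± 0.37) and Irg1 (0.21 ± 0.57) were not called. Interferon genes fell in 12 of 34 cases, 25 adjusted over the list alone (camera adjusted p = 9.49e-35, and adjusted p = 0.00239 with an estimated correlation). Cholesterol genes rose in 8 of 22, 12 adjusted over the list alone (Fdps, 3.30 ± 0.53; camera adjusted p = 4.98e-21, and adjusted p = 0.00239 with an estimated correlation). NRF2 genes rose in 2 of 25 (8 adjusted over the list alone; Slc7a11, 2.49 ± 0.40; camera adjusted p = 1.40e-07, and adjusted p = 0.137 with an estimated correlation). Mitochondrially encoded transcripts rose in 3 of 11 (8 adjusted over the list alone; camera adjusted p = 1.33e-13, and adjusted p = 0.0635 with an estimated correlation). The chemokine list was lower (3 of 12 higher, 5 lower; camera adjusted p = 0.000321, and adjusted p = 0.142 with an estimated correlation). With 21 libraries camera called it higher (adjusted p = 0.00199, and adjusted p = 0.451 with an estimated correlation), against a median of -0.83 and a mean of -0.27. Lipid-handling (3 of 15) and HIF-1 target lists had higher medians, and feedback and ATF4 target lists lower ones. These calls were lost with an estimated correlation (camera adjusted p from 0.00064 to 0.0306, and adjusted p from 0.0802 to 0.369 with an estimated correlation). With 21 libraries camera called the feedback list higher (median 0.54; adjusted p = 0.00836, and adjusted p = 0.472 with an estimated correlation). The neutrophil-marker list was higher (3 of 5; camera adjusted p = 4.97e-08, and adjusted p = 0.00295 with an estimated correlation), with S100a9, Ppbp and Itga2b at 0 and Pf4 at 308 CPM in that library. edgeR called 13 genes with 21 libraries (11 higher, 2 lower; 10 and 0 with median-of-ratios size factors, 21 and 33 with DESeq2) and 99 with 20 (60 higher, 39 lower). It called 1170 when LPS replicate 2 was left out, with the library labelled LPS 48 h replicate 1 as LPS, and there Ccl7, Ccl2, Il1rn and Slc28a2 turned to higher.

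DMM is the dimethyl ester of malonate, a dicarboxylate with 1 methylene group fewer than succinate. The compounds were compared at the same times; whether the doses matched is not given in the sources used here. Without LPS in the 4 h set, Ch25h (2.84 ± 0.65), the actin-binding Lsp1 (1.92 ± 0.30), Il17re, Dab2, Mrc1 and the clone-named AC242409.1 and AC131780.1 were higher with DMM. Atp6v0d2 (-3.65 ± 0.48), the immediate early gene Junb, the apolipoprotein Apoc2 (-1.98 ± 0.35), Sgk1, Ahnak2, Npy, Slc5a3 and the lipase Pnpla2 (-1.60 to -1.71) were lower. The cell cycle list was higher (1 of 34, 12 adjusted over the list alone; camera adjusted p = 3.65e-10, and adjusted p = 0.00127 with an estimated correlation). Interferon and heat shock lists had lower medians (camera adjusted p from 0.00037 to 0.0372, and adjusted p from 0.194 to 0.432 with an estimated correlation). Il1b (-0.79 ± 0.70), Tnf (-0.11 ± 0.61) and the other panel genes were not called in either set. After 48 h, cholesterol synthesis genes were lower with DMM than with succinate in 9 of 22 cases, 16 adjusted over the list alone (Idi1, -1.83 ± 0.29; Sqle, -1.70 ± 0.33; Hmgcs1, -1.65 ± 0.29; Sc4mol, also called Msmo1, -1.64 ± 0.28; camera adjusted p = 7.77e-35, and adjusted p = 0.000258 with an estimated correlation). Lipid-handling genes were lower in 2 of 15 (7 adjusted over the list alone; the fatty acid binding Fabp5, -2.34 ± 0.41; camera adjusted p = 2.53e-11, and adjusted p = 0.00436 with an estimated correlation). Slc5a3, Atp6v0d2 and Apoc2 were lower too (-1.68 to -2.23). Cell cycle (4 of 34 higher adjusted over the list alone) and MHC class II genes (1 of 9) were higher as lists (camera adjusted p from 1.54e-13 to 3.07e-05, and adjusted p from 0.000258 to 0.00933 with an estimated correlation). Oxidative phosphorylation, mitochondrially encoded, lysosome and macrophage identity lists had lower medians. Their calls were lost with an estimated correlation (camera adjusted p from 1.98e-05 to 0.0491, and adjusted p from 0.464 to 0.629 with an estimated correlation). Ch25h (2.40 ± 0.38), Pf4 (2.30 ± 0.34), Ly6a, Parvg, Smpdl3b, the iron exporter Slc40a1, Tnfrsf26 and H2-Ab1 (1.57 to 2.64) were higher. edgeR called 1 gene in the 4 h set with 21 libraries, Atp6v0d2, and 29 with 20 (15 higher, 14 lower; 57 in the 4 h set alone). For the 48 h set it called 0 (248 at an unadjusted p under 0.05; DESeq2 2) and 31 (13 higher, 18 lower); both groups held 2 libraries. Without any 1 of the 4 libraries of its groups the 4 h count was 0 (230 to 467 at an unadjusted p under 0.05; DESeq2 12 with all libraries).

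Under LPS in the 4 h set, DMM then LPS had lower Mmp9 (-7.45 ± 0.43), Cxcl3 (-7.30 ± 0.35), Pf4 (-5.34 ± 0.38), Cxcl1 (-4.84 ± 0.40) and Cxcl2 (-3.88 ± 0.34) than succinate then LPS. Lower too were Irg1 (-1.82 ± 0.47), Hif1a (-1.22 ± 0.39), Tnf and Il1b (-1.70 ± 0.46). Higher were Ccl7 (3.45 ± 0.49), Il1rn (3.11 ± 0.46) and the antiviral Rsad2 (3.15 ± 0.50). The stromal proteoglycan gene Dcn was at least 8.48-fold and Slc28a2 at least 6.65-fold higher, and Slfn10-ps, Map3k3, Zmym2, Tigd2, Zc3h10 and Rgs1 were at least 2.65 to 3.95-fold higher. Scd1 was 73.7-fold (95% counting interval 11.8 to 3060) and the desaturase Fads2 33.2-fold (95% counting interval 4.6 to 1450) lower; Eef1a1 (-4.22 ± 0.49) and Actg-ps1 (-5.60 ± 1.18), which share reads with copies, fell. Cholesterol genes were lower in 13 of 22 (15 adjusted over the list alone; camera adjusted p = 7.99e-14, and adjusted p = 0.00523 with an estimated correlation). NRF2 genes were lower in 11 of 25 (14; camera adjusted p = 9.79e-05, and adjusted p = 0.327 with an estimated correlation). Oxidative phosphorylation genes were lower in 16 of 57 (26; camera adjusted p = 1.51e-08, and adjusted p = 0.337 with an estimated correlation) and mitochondrially encoded transcripts in 8 of 11 (camera adjusted p = 2.49e-07, and adjusted p = 0.219 with an estimated correlation). Interferon genes were higher in 6 of 34 (8 adjusted over the list alone; camera adjusted p = 0.000341, and adjusted p = 0.326 with an estimated correlation). Glycolysis, unfolded protein response (7 of 20), lipid-handling, macrophage identity, pro-inflammatory and lysosome lists were called lower. These calls were lost with an estimated correlation (camera adjusted p from 4.62e-05 to 0.0486, and adjusted p from 0.0651 to 0.604 with an estimated correlation). The neutrophil markers were lower in 4 of 5 (camera adjusted p = 5.56e-10, and adjusted p = 0.00358 with an estimated correlation). For chemokines the median (0.74) and the mean (-0.08) differed in sign, and camera called the list lower (camera adjusted p = 0.0373, and adjusted p = 0.338 with an estimated correlation). edgeR called 233 genes with 21 libraries (23 higher, 210 lower), 710 with 20 (126 higher, 584 lower) and 910 in the 4 h set alone. With 21 libraries it called 17 without DMM then LPS replicate A and 93 without replicate B.

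The 48 h set gave lower Hif1a (-1.34 ± 0.39), Tnf (-1.15 ± 0.32), Il1b (-3.83 ± 0.47), Pf4 (-7.03 ± 0.42), Mmp9 (-7.00 ± 0.44) and Cxcl2 (-4.29 ± 0.38) with DMM than with succinate. Lower too were Serpinb2 (-4.61 ± 0.44), Slpi (-4.35 ± 0.48) and isocitrate dehydrogenase Idh1 (-3.35 ± 0.39). Cxcl3 was 181-fold (95% counting interval 61.2 to 887) lower, and the desaturase Fads2 was at least 10.4-fold lower. Nos2 (2.44 ± 0.44), Il1rn (4.02 ± 0.50), Ccl7 (4.15 ± 0.55), Fgl2 (4.64 ± 0.57) and Ifit2 (4.03 ± 0.48) were higher. Cd5l was 36.9-fold (95% counting interval 12.5 to 180) and Cxcl10 20.4-fold (95% counting interval 5.5 to 170) higher, Mx1 21.1-fold (95% counting interval 5.71 to 177) higher, and Ccl8, Tmem237, Zscan29 and Dcn at least 3.04 to 3.91-fold higher. Interferon genes were higher in 12 of 34 (21 adjusted over the list alone; camera adjusted p = 7.51e-14, and adjusted p = 0.0245 with an estimated correlation). Cholesterol genes were lower in 13 of 22 (15; camera adjusted p = 2.72e-19, and adjusted p = 0.00223 with an estimated correlation) and mitochondrially encoded transcripts lower in 10 of 11 (camera adjusted p = 1.63e-16, and adjusted p = 0.028 with an estimated correlation). Unfolded protein response (6 of 20), lipid-handling (6 of 15) and neutrophil-marker genes (3 of 5) were lower as lists (camera adjusted p from 1.09e-09 to 6.27e-05, and adjusted p from 0.00223 to 0.039 with an estimated correlation). Oxidative phosphorylation, NRF2, glycolysis, pentose phosphate and macrophage identity lists were called lower and the apoptosis list higher. These calls were lost with an estimated correlation (camera adjusted p from 1.48e-05 to 0.0398, and adjusted p from 0.0923 to 0.431 with an estimated correlation). edgeR called 81 genes with 21 libraries (19 higher, 62 lower) and 460 with 20 (123 higher, 337 lower). With 21 libraries, 20 were called without DMM then LPS replicate 1 and 183 without replicate 2; the succinate group held 1 library in each set.

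The sets were compared by the difference of their effects. For the effect of LPS, 48 h minus 4 h, Fgl2 was higher (4.07 ± 0.82) and the unannotated Gm9877 lower (-4.00 ± 0.67) with 20 libraries. Pf4 was called lower, with 1 group at 0 counts and no size given. For the effect of DMM under LPS, the interferon-inducible Ifi205 was higher (2.84 ± 0.52). No panel gene was called for either difference. Interferon genes had higher medians in both (0.50 and 0.44), NRF2 genes a lower one for LPS (-0.48), and lysosome and macrophage identity genes higher ones for DMM under LPS. These calls were lost with an estimated correlation (for LPS, camera adjusted p from 0.00054 to 0.0029, and adjusted p from 0.452 to 0.462 with an estimated correlation; for DMM, camera adjusted p from 0.00646 to 0.0152, and adjusted p = 0.792 with an estimated correlation). With 21 libraries camera called the interferon list lower for LPS (median -0.23; adjusted p = 0.0247, and adjusted p = 0.835 with an estimated correlation). These 3 and 1 genes compare with 0 and 0 with all 21 libraries (534 and 715 at an unadjusted p under 0.05; DESeq2 3 and 6), 786 and 1247 without LPS 48 h replicate 2, and for DMM 12 without DMM then LPS 48 h replicate 1. Across genes, which are not independent replicates, the DMM effects of the sets had Pearson r = 0.238 and Spearman rho = 0.296 with 21 libraries, and 0.509 and 0.558 with 20. These effects share no library. In the 20-library fit, 121 genes were lower with DMM in both sets, against 16.87 for independent lists, 26 were higher in both, against 2.1, and 0 had opposite calls. The 200 genes with the smallest p among those higher with LPS in the 4 h set had a median DMM effect of -0.78 in the 48 h set (55 lower, 2 higher; camera p = 8.77e-35, and p = 0.00905 with an estimated correlation). The 200 lower with LPS had a median of 0.47 (9 higher, 1 lower; p = 5.45e-05, and p = 0.07 with an estimated correlation). With all 21 libraries both medians had the opposite sign, 0.13 and -0.82. These lists came from the 4 h libraries, which the 48 h contrast does not hold.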

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

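The interaction tests with 21 libraries (edgeR and DESeq2), those with single libraries of their groups left out and the test of the difference of the LPS effects were planned; the 4 h interaction count without the library labelled LPS 48 h replicate 1 and all other tests of this part were chosen only after the results had been seen. The effect of DMM differed between cells with and without LPS in both sets. The interaction test of edgeR called 78 genes in the 4 h set and 2 in the 48 h set with all 21 libraries, and 447 and 22 without the library labelled LPS 48 h replicate 1. The 2 genes of the 48 h set were Ch25h (-5.09 ± 0.80 on the log2 scale ± SE) and Tmem176b (-3.59 ± 0.54, 21 libraries). Without any 1 library of its groups the 4 h count was 5 to 42, lowest without DMM then LPS replicate A. The 48 h count was 0 without DMM replicate 2 or DMM then LPS replicate 2 (458 and 608 at an unadjusted p under 0.05; DESeq2 with all libraries 27) and 613 without LPS replicate 2.

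The library labelled LPS 48 h replicate 1 lay among the unstimulated libraries, with 33.8 CPM of Saa3 against 98269.4 CPM in replicate 2. A separate culture in which the stimulation failed should differ from other cultures at least as much as replicates do, but its chi-square per degree of freedom with DMM 48 h replicate 1, with all libraries thinned to 662186 counts, was 1.152. The 8 pairs within a group, this library aside, gave 2.377 to 10.838, and the log2 ratio to the lowest was -1.05. A swap with a library labelled unstimulated would leave one of those at the stimulated level of Saa3, and 0 of 11 lay there (highest 109.3 CPM). The value of 1.152 is consistent with material of DMM 48 h replicate 1 under both labels, which is a hypothesis; no biological explanation was tested, since the design gives none.

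Cytosolic ribosomal protein genes were lower with DMM then LPS than with LPS alone in the 4 h set (median log2 fold change -2.26, SD 0.76, 71 of 81 called lower). Loss of short transcripts may be part of this, as 154 other genes matched on length and level had a median of -0.84 (SD 0.95, 68 lower). The ribosomal protein median differed from theirs by -1.43 (95% interval from 10000 resamples of genes, not independent, -1.59 to -1.23). Library sizes without the 50 most abundant genes moved the median of all genes to 0.85 and of ribosomal protein genes to -1.46 (65 lower). Such a shift of all genes alike cannot test abundant genes as a cause. For the 57 oxidative phosphorylation genes (median -0.88) the difference to 146 matched genes was -0.25 (95% interval -0.53 to 0.02), so a fall beyond theirs stays open. Other lists were not matched. An effect of DMM under LPS on the ribosomal protein genes stays open, since in the 48 h set their median was -0.80 with 6 lower, and the list test gave camera p = 2.65e-18 but p = 0.175 with an estimated correlation.

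The LPS effects of the 4 h and 48 h sets, which share no library, were alike across genes (Pearson r = 0.796, Spearman rho = 0.699). In the 20-library fit, 600 genes were higher in both sets, against 104.63 for independent lists, 411 were lower in both, against 64.66, 2 had opposite calls and 3 were called for the difference. LPS 48 h replicate 2 had a chi-square per degree of freedom of 6.472 and 6.493 with the 4 h LPS libraries at equal depth, against 2.58 between those and 2.377 to 10.838 over the pairs within a group without the library labelled LPS 48 h replicate 1, so that LPS libraries of both sets made from the same material are not excluded. A similar length of exposure to LPS in both sets could also give such a likeness, as could a response to LPS that lasts from 4 to 48 h. The correlation of 0.796 does not decide between them, and with 1 LPS and 1 control library in the 48 h fit the length of exposure cannot be told apart from other differences of the sets.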

How the results depend on the processing

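Chosen after seeing the data were the fits with merged unstimulated groups, DESeq2 with 20 libraries, the 48 h set alone without the library labelled LPS 48 h replicate 1, and the 20-library fit for comparisons without the LPS 48 h group, lists and other-set genes; the rest was planned. All counts are genes called at an adjusted p under 0.05. Median-of-ratios size factors moved no count by over 1.5 times and left 363 of 364 named gene results on their side of the threshold. In simulated data at this depth, the test of DMM before LPS at 4 h recovered 3% of 2-fold and 46% of 4-fold changes with 21 libraries, and 18% and 79% with 20. The planned lists of LPS genes of the 48 h set gave no value with 21 libraries, since edgeR called 0 genes there (769 at an unadjusted p under 0.05; DESeq2 114).

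Deviations of same-numbered libraries correlated at -0.053 to 0.131 over 10 pairs of groups at 4 h and 0.039, -0.012 and 0.258 at 48 h. Counting error lowers these values, so pairing by number stays open. With a replicate block, edgeR called 120 genes for the interaction at 4 h, 33 for succinate before LPS at 48 h, 180 for DMM against succinate under LPS at 48 h, and 0 (466 at an unadjusted p under 0.05; DESeq2 without the block 12) and 1 for DMM against succinate alone at 4 and 48 h. The other counts stayed within 1.5 times, and of the named gene results 7 lost and 12 gained a call. Of the list tests 141 were called, against 145 without the block.

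With the 4 h libraries alone, edgeR called 1956 genes for LPS, 104 for DMM and 3 for succinate alone, 1435 for DMM and 173 for succinate before LPS, 640 for the interaction, and 57 and 910 for DMM against succinate without and with LPS. These counts leave out the doubted library. With the 48 h libraries alone it called 0 for each of 8 comparisons (65 to 538 at an unadjusted p under 0.05; DESeq2 with 21 libraries 2 to 127). Without the doubted library these libraries gave 1078 for LPS, 3 for DMM alone, 87 and 67 for DMM and succinate before LPS, 11 for the interaction, and 26 and 299 for DMM against succinate.

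Without a filter on low counts the 48 h set gave 155 genes for LPS, 3 for DMM alone, 258 and 112 for DMM and succinate before LPS, 107 for the interaction, and 8 and 172 for DMM against succinate without and with LPS. The 4 h set gave 43 and 2 for DMM and succinate alone, 42 for succinate before LPS, 219 for the interaction and 6 for DMM against succinate. The differences between sets gave 44 for LPS and 63 for DMM under LPS. Of the named gene results 14 lost and 62 gained a call, and with DESeq2 and 21 libraries 27 and 51. The cause was not tested.

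DESeq2 called, in the same order for the 48 h set, 114, 4, 117, 54, 27, 2 and 127 genes, and 2 for succinate alone. For the 4 h set it called 24 and 1 for DMM and succinate alone, 178 for the interaction and 12 for DMM against succinate, and for the differences between sets 3 and 6. With 20 libraries DESeq2 called, in that order for the 48 h set, 699, 1, 134, 56, 18, 19 and 308. For the 4 h set it called 54 for DMM alone, 705 and 82 for DMM and succinate before LPS, 360 for the interaction, and 29 and 506 for DMM against succinate. The differences between sets gave 1 and 7. The cause was not tested.

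With merged unstimulated groups edgeR called 502 genes for LPS at 48 h, 8 and 6 for succinate before LPS at 4 and 48 h, 57 for the interaction at 48 h and 1 for DMM against succinate. Merged and without the doubted library it called 1414 for LPS at 48 h, 38 for DMM alone, 956 for DMM before LPS at 4 h, 70 and 38 for succinate before LPS, 370 and 27 for the interactions, and 15 and, under LPS, 516 and 263 for DMM against succinate. Merging gave LPS at 48 h 3 control libraries in place of 1.

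Leaving out 1 library at a time, the library labelled LPS 48 h replicate 1 included, gave 418 to 1869 and 1 to 1217 genes for LPS at 4 and 48 h. DMM alone gave 0 to 71 and 0 to 2, DMM before LPS 14 to 1230 and 0 to 1275, succinate before LPS 6 to 131 and 99 to 1170, and the interactions 5 to 447 and 0 to 613. DMM against succinate gave 0 to 29 and 0 to 31 alone and 17 to 710 and 20 to 460 under LPS, and the differences between sets 0 to 786 and 0 to 1247. The lone library of an arm was then assumed to vary like the other groups. Where such a range starts at 0, the fits with 0 calls held 156 to 727 genes at an unadjusted p under 0.05 by edgeR, and DESeq2's counts with all libraries are above. The highest counts came without LPS 48 h replicate 2 for DMM and succinate before LPS at 48 h, the interaction at 48 h and both differences between sets, where the doubted library stood alone for LPS, and otherwise without the doubted library. Of the named gene results 0 to 31 lost their call without 1 library. The correlation of the DMM effects ran from -0.047 (without LPS 48 h replicate 2) to 0.509, and was 0.058 without DMM then LPS 48 h replicate 1.

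Of 432 list tests 145 were called with 21 libraries, 9 with an estimated correlation, 50 with fry and 131 without the doubted library, of which 110 were called in both and 6 in opposite directions; an estimated correlation without that library left 42. The lists that turned were the chemokine (0.00109), glycolysis (0.00903) and pro-inflammatory lists (0.0454) with DMM before LPS at 48 h. Those with succinate before LPS at 48 h were the feedback (0.0209) and chemokine lists (0.000321), and the interferon list turned for the difference of LPS effects (0.00054, adjusted p without that library). With an estimated correlation none of these 6 was called, with adjusted p from 0.142 to 0.466 without that library and from 0.451 to 0.835 with it. The medians of the LPS genes of the 4 h set in the DMM effect at 48 h turned to -0.78 and 0.47 without it, and with 21 libraries their p was 0.515 and 0.283 with an estimated correlation and 0.478 and 0.161 with fry.

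Without that library Trem2 turned to higher with DMM before LPS at 48 h (3.25; DESeq2 3.29, merged 3.25, 48 h set alone 3.32), in its interaction (3.72; DESeq2 3.76, merged 3.77) and with succinate before LPS (4.32; DESeq2 4.36, merged 4.32, 48 h set alone 4.33), as did Crip1 there (4.25; merged 4.25). Leaving out each library in turn, the log2 fold changes with DMM before LPS at 48 h ran from -3.49 to 3.25 for Trem2, -2.25 to 10.47 for Ccl7, -3.89 to 2.90 for Gpr84, -2.75 to 9.58 for Il1b, -3.39 to 6.50 for Mmp9, -4.01 to 6.58 for Serpinb2, -2.61 to 3.91 for Slc7a2, -1.34 to 2.27 for Tnip1 and -1.31 to 3.93 for Tnf. With succinate before LPS they ran from -2.42 to 4.32 for Trem2, -3.53 to 4.25 for Crip1, -2.97 to 7.47 for Ccl2, -6.40 to 6.31 for Ccl7, -2.64 to 3.27 for Il1rn and -3.22 to 5.64 for Slc28a2, and in the interaction from -3.04 to 3.72 for Trem2. The positive ends of Ccl7, Gpr84, Il1b, Mmp9, Serpinb2, Slc7a2, Tnip1, Tnf, Ccl2, Il1rn and Slc28a2 came without LPS 48 h replicate 2.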

Other observations

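The counts of other splits, the overlap of the succinate effects between sets, the merged groups and the use of the fit without the library labelled LPS 48 h replicate 1 for the values of this part were chosen only after the results had been seen. Single genes of central carbon metabolism moved under LPS although the TCA cycle list was not called. In the 4 h set 5 of 24 TCA cycle genes fell and 2 rose. The cytosolic malate dehydrogenase Mdh1 fell by 2.42 ± 0.31 on the log2 scale (± SE) and the fumarate hydratase Fh1 by 1.65 ± 0.37, and Mdh1 (-2.34 ± 0.42) and Fh1 (-1.78 ± 0.47) fell in the 48 h set too. With DMM before LPS, against LPS alone at 4 h, 5 of 24 TCA cycle genes fell, among them Mdh2 (-0.98 ± 0.29), as did the mitochondrial dicarboxylate carrier Slc25a10 (-1.24 ± 0.36). Of 15 pentose phosphate and nucleotide synthesis genes 3 fell, the dehydrogenases G6pdx (-1.81 ± 0.29) and Pgd (-0.97 ± 0.34) and the transketolase Tkt (-1.67 ± 0.33). Neither list was called by camera (adjusted p = 0.514 and 0.477). The hexose transporter Slc2a6 fell with DMM before LPS in both sets (-1.20 ± 0.27 and -1.94 ± 0.32). With succinate before LPS the aldolase gene Aldoc was higher in both sets (2.39 ± 0.34 and 2.76 ± 0.42).

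The NF-kB inhibitor gene Tnip1 rose with LPS in both sets (3.79 ± 0.34 and 4.46 ± 0.54) and was lower with DMM before LPS than with LPS alone (-1.37 ± 0.27 and -1.34 ± 0.32). The stress-responsive transcription factor Atf3 was higher with DMM before LPS at 4 h (1.14 ± 0.31). The folate enzyme Mthfd2 rose with LPS at 4 h (2.24 ± 0.31) and was lower with DMM before LPS (-1.07 ± 0.27), and the pore-forming gasdermin gene Gsdmd (-1.04 ± 0.27) and the cholesterol exporter Abcg1 (-1.88 ± 0.37) fell in that comparison. With succinate before LPS at 4 h the Fc receptor gene Fcgr1 (-1.92 ± 0.46) and the checkpoint ligand Cd274 (-1.95 ± 0.45) fell and catalase (Cat, 1.44 ± 0.37) rose. The stromal marker Acta2 rose with LPS at 4 h (3.15 ± 0.67) and fell with DMM before LPS (-2.80 ± 0.58). Of the other stromal markers Dcn was tested, of the dendritic markers only Bst2 (2.21 ± 0.36 with LPS at 4 h), of the B cell markers only Ighm and of the erythroid and megakaryocyte markers only Pf4; no T and NK cell or mast cell marker was tested.

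With succinate before LPS, 37 genes rose in both sets, which the 2-library filter favours (1 such library per set). In both 23 fell, against 0.37 for independent lists, and 0 had opposite calls (Pearson r across genes 0.225). The 200 genes with the smallest p among those higher with LPS in the 48 h set had a median DMM effect of -1.08 under LPS in the 4 h set (5 higher, 126 lower; camera p = 6.57e-42, and p = 0.00572 with an estimated correlation). The 200 lower with LPS had one of 0.14 (p = 0.0704, and p = 0.334 with an estimated correlation).

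With unstimulated libraries merged over both sets, edgeR called 38 genes between DMM and control, and of the 35 splits of these 7 libraries 1, the real one, gave as many (highest other 11). Between DMM and succinate 15 genes were called and 2 of the 35 splits gave as many, the other with 59; within the sets 29 and 31 genes were called. The splits with 11 and 59 parted the 4 h from the 48 h libraries. In each of these comparisons 18 splits kept the number of libraries per set, which is too few for a share under 0.05, and apart from the real ones they gave at most 1 gene. Between succinate and control 0 genes were called by edgeR (363 at an unadjusted p under 0.05; DESeq2, not merged, 0 in each set with 20 libraries, and 1 and 2 with 21), so that all 35 splits gave as many by construction and the count of splits tests nothing. The highest, 157, was again the split of 4 h from 48 h libraries, which points to a structure of the samples that follows the sets as inferred from the numbering.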
